A study of Mus musculus with 8 samples.

How the data were processed

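RelA ChIP-seq was carried out in primary embryonic fibroblasts of wild-type C57BL/6 mice after overnight serum starvation and TNF at 10 ng/ml, with 2 libraries at each of 0, 0.5 and 3 h and 2 input DNA libraries. Per the labels' protocols, chromatin was cross-linked with disuccinimidyl glutarate and then formaldehyde, sheared by sonication and precipitated with an antibody against p65, and libraries were made with the NEBNext Ultra kit without size selection. Cross-linking with both agents can retain proteins that touch DNA through other proteins, so a peak need not hold a site that RelA itself contacts. Per the submitters' processing notes, cutadapt 1.9.1, Bowtie2 2.3, SAMtools, Picard 1.13, deepTools and MACS2 were used with the mm10 genome. Which tool did which step, the peak threshold, the use of the input libraries, and whether peaks were called per library, per time or on pooled libraries are not given in the sources used here. The deposited values are the chromosome, start and end of each peak in base pairs, in 3 columns, with no score, height or p-value and no column per sample. The input and ChIP libraries could not be told apart in these values, so no library entered a comparison on its own, depth was unknown, and no background level could be given.

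Starts were converted to positions counted from 1. Gene positions, kinds and symbols came from an NCBI RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 49209 genes on chromosomes 1 to 19 and X, of which 21521 were protein-coding. In addition, 345 genes whose positions refer to patch or unplaced scaffolds were left out. The table carries no strand and no exons, and no genome sequence was used here. The planned start-site distances were therefore replaced by distances from the peak centre to either end of a gene. The planned tests of promoter, exon and untranslated region classes, of kappaB and other motifs, and of kappaB sequence variants were not run. The planned test of binding by time was not run either, for lack of values per sample. The 6 peaks on contigs without a position on a chromosome entered only the description of the whole list and the ranking by width.

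Before the data were examined, 19 gene lists were written from general knowledge: NF-kB inhibitors and negative feedback, NF-kB and IKK subunits, TNF receptor signalling proteins, chemokines, cytokines and growth factors, cell survival genes, cell adhesion and surface receptors, antigen presentation, interferon response, matrix remodelling and prostaglandin enzymes (with acute-phase genes), immediate early genes, fibroblast identity and extracellular matrix, housekeeping genes, and markers of macrophages, endothelium, epithelium and keratinocytes, neurons, hepatocytes and skeletal muscle. Of 321 distinct symbols, 318 matched a protein-coding gene. Cxcl11, Mx1 and Mx2 are annotated as pseudogenes in the gene table and were left out, and Birc2, Birc3 and Traf1 stood in more than 1 list. For each list, the share of genes with a peak centre within 10 kb of a gene end was compared with all other protein-coding genes by a two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 19 lists, at a threshold of 0.05. Wilson 95% intervals cover counting error only. Neighbouring genes can share a peak, which the test does not model. Location, distance and clustering were compared with 1000 random placements of the peaks on their own chromosome between its first and last gene, and peaks per chromosome with placements over all chromosomes. These are called permutation tests of peak positions below, with two-sided p-values that cannot fall below 0.002. The placements drew new positions uniformly, so the spacing of the observed peaks was not kept. Tests against matched lists, described below, likewise drew random genes. The placements do not exclude sequence that short reads cannot be assigned to.

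Named genes followed a rule set before the data were examined: every gene of the inhibitor and subunit lists within 10 kb of a peak, the 3 genes closest to a peak in each other list if within 10 kb, the 10 genes with the most peaks within 50 kb, and the genes nearest to the 10 widest peaks. A gene that the rule names is not reported here. Genes outside the rule are said to have been named after their values were seen, which also holds for Icam1 in the map of regions, for the genes named as sharing a peak and for all genes in the closing observations. The alternatives were windows of 1, 5 and 50 kb, the nearest gene end only, the wider peaks only, neighbouring list genes counted once, protein-coding ends only, any overlap in place of the centre, and peaks within 1 kb merged. The nearest-end alternative counted ends up to 100 kb from the peak centre, so it was not a narrower form of the 10 kb window. Further alternatives, chosen after seeing the data, were rotation of all peaks along each chromosome, placement matched on the distance to a gene end, adding peaks inside genes, 10000 random lists matched on gene length and density of gene ends (in place of the planned match on base composition), an expectation per chromosome from autosomal rates, and placement over the autosomes only.

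The procedures were tested on 20 simulated sets of 9823 peaks over the same 21521 protein-coding genes. Peaks of the unchanged sets were placed uniformly at random, without the excess at gene ends or the clusters of the real list. In these sets, 0 of 380 lists were called by Fisher's exact test, and also 0 by the matched lists. This does not give the rate of false calls for peaks placed like the real ones. When 10% of peaks were moved to gene ends, the excess was called in 20 of 20 sets, and planted pairs were called as clusters in 20 of 20. When 60% of the genes of chosen lists were given a peak, 100 of 100 such lists were called, and 2 of 280 other lists were called too. The planted peaks lay inside the windows that were then scored, so these calls do not measure power for weaker or more distant patterns. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.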

Results

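Binding of RelA (p65), a subunit of NF-kB that activates transcription, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in primary fibroblasts from wild-type C57BL/6 mouse embryos. Serum-starved cells were treated with TNF, an inflammatory cytokine that activates NF-kB, at 10 ng/ml. ChIP libraries were made at 0, 0.5 and 3 h, with 2 libraries per time, beside 2 input DNA libraries, which gave 8 libraries in all. The values analysed were 1 list of 9829 RelA peaks, each a start and an end on the mm10 mouse genome, with no height, score or sample attached. The peaks could be related to genes, but the 3 times could not be compared, the depth of each library was unknown, and no spread between replicates could be calculated. All tests below therefore compared this single list with chance placement or with other genes, and their p-values carry no information on the spread between cultures. Peaks had a median width of 687 bp, with quartiles of 587 and 816 bp and a range of 301 to 2015 bp, and together covered 7.10 Mb. No direction of transcription was used. The distance of a gene to a peak is therefore the distance from the peak centre to the nearer of its ends. Either end of a protein-coding gene can be the start site.

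The first question was which genes of the NF-kB and TNF response lay near RelA peaks. Genes of the list of NF-kB inhibitors and negative feedback had the highest share of the 19 gene lists tested at 10 kb. Of these genes, 12 of 14 (85.7%, Wilson 95% interval 60.1 to 96.0%) had a peak centre within 10 kb of a gene end, against 17.1% of all other protein-coding genes (odds ratio 29.1, Fisher's exact test, adjusted p = 7.80e-07). Chemokines ranked higher with neighbouring genes counted once (8 of 9), and antigen presentation genes at 50 kb (14 of 15 against 13 of 14). The I-kappa-B genes Nfkbia, Nfkbib and Nfkbie, which encode proteins that hold NF-kB in the cytoplasm, had peak centres 0.190, 0.215 and 0.084 kb from a gene end. At Nfkbia on chromosome 12, positions 55489409 to 55492647, the peak spanned 55492275 to 55493400 and was 1 of 3 peaks within 10 kb. Peaks also lay at the nuclear I-kappa-B genes Nfkbiz (0.031 kb), Nfkbid (0.325 kb) and Bcl3 (0.091 kb, 4 peaks within 10 kb). Tnfaip3 on chromosome 10, positions 19000910 to 19015410, encodes the ubiquitin-editing enzyme A20, and a 1077 bp peak was centred 0.033 kb from its end. The genes for the A20-binding proteins Tnip1 and Tnip3 had peaks at 0.115 and 0.053 kb, with 5 peaks within 10 kb of Tnip1. The deubiquitinase gene Cyld had a peak at 0.084 kb, and the genes for the RNA-degrading protein Zc3h12a and the RNA-binding protein Zfp36 had peaks at 2.98 and 2.37 kb. The 2 members without a peak within 10 kb, named after their values were seen, were Otud7b (16.5 kb) and Tnip2 (459 kb).

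Genes for NF-kB itself and for its activating kinases were near peaks in 9 of 11 cases (81.8%, Wilson 95% interval 52.3 to 94.9%, Fisher's exact test, adjusted p = 1.90e-05). All 5 NF-kB subunit genes had a peak. The nearest peak centre lay at 0.205 kb for Rela (chromosome 19, peak 5636477 to 5637997), 0.034 kb for Relb, 0.134 kb for Rel and 0.211 kb for Nfkb1. Nfkb2 had a 1610 bp peak inside the gene, 4.06 kb from its end. The kinase genes Ikbkb, Ikbke, Tbk1 and Map3k14 had peaks at 1.64, 0.704, 0.632 and 0.392 kb. Chuk (160 kb) and Ikbkg (478 kb), named after their values were seen, had none within 10 kb. Genes for proteins that carry the signal from the TNF receptors were near a peak in 10 of 18 cases (55.6%, Wilson 95% interval 33.7 to 75.4%, Fisher's exact test, adjusted p = 5.24e-04). Birc3 (0.138 kb), which encodes a ubiquitin ligase of the receptor complex, and the kinase genes Map3k8 (0.332 kb) and Map3k7 (0.398 kb) were the closest.

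Genes for secreted mediators of inflammation followed. Among chemokines, which attract leukocytes, 12 of 18 genes were near a peak (66.7%, Wilson 95% interval 43.7 to 83.7%, Fisher's exact test, adjusted p = 1.90e-05), and 9 of them had one within 1 kb. Cxcl5 had a peak centre 0.002 kb from its end (chromosome 5, 90759032 to 90759560), Ccl20 at 0.032 kb and Ccl5 at 0.145 kb. Among cytokines and growth factors, 12 of 23 genes were near a peak (52.2%, Wilson 95% interval 33.0 to 70.8%, Fisher's exact test, adjusted p = 3.12e-04). A 1014 bp peak lay 0.015 kb from the end of Il6 (chromosome 5, 30012593 to 30013606), and Csf1, the macrophage growth factor gene, had one at 0.073 kb. The peak nearest to Tnf (0.186 kb) was also the nearest to its neighbours Lta and Ltb. With the window narrowed to 1 kb, 4 cytokine genes were near a peak and the group no longer passed Fisher's exact test (adjusted p = 0.103).

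Surface and antigen presentation genes were also near peaks. Of the genes for adhesion molecules and surface receptors, 11 of 16 were near a peak (68.8%, Wilson 95% interval 44.4 to 85.8%, Fisher's exact test, adjusted p = 2.20e-05), led by the interleukin-4 receptor gene Il4ra (0.069 kb), Madcam1 (0.083 kb) and the syndecan gene Sdc4 (0.102 kb). Icam1, named after its values were seen, had 5 peaks within 10 kb. Antigen presentation genes were near a peak in 12 of 15 cases (80.0%, Wilson 95% interval 54.8 to 93.0%, Fisher's exact test, adjusted p = 1.64e-06). A peak lay 0.024 kb from B2m, which encodes the light chain of class I molecules (chromosome 2, 122147263 to 122148063), and the class I heavy chain genes H2-Q4 and H2-D1 had peaks at 0.098 and 0.113 kb. The class I genes are close copies of each other, as are the Gbp genes below, so the placement of reads among them is uncertain. A single peak was the nearest to both Tap1 and Psmb9, and another was the nearest to Psme1 (9.74 kb), Psme2 and Rnf31. Interferon response genes were near a peak in 9 of 21 cases (42.9%, Wilson 95% interval 24.5 to 63.5%, Fisher's exact test, adjusted p = 0.00814). Among its closest members were the transcription factor gene Irf1 (0.017 kb) and the GTPase gene Gbp2 (0.123 kb). This group no longer passed Fisher's exact test with a 50 kb window (adjusted p = 0.104) or when peaks inside genes were added (adjusted p = 0.0618). Nor did it pass the exact test when each peak was given to the nearest gene within 100 kb alone (adjusted p = 0.166).

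**Figure D1:**
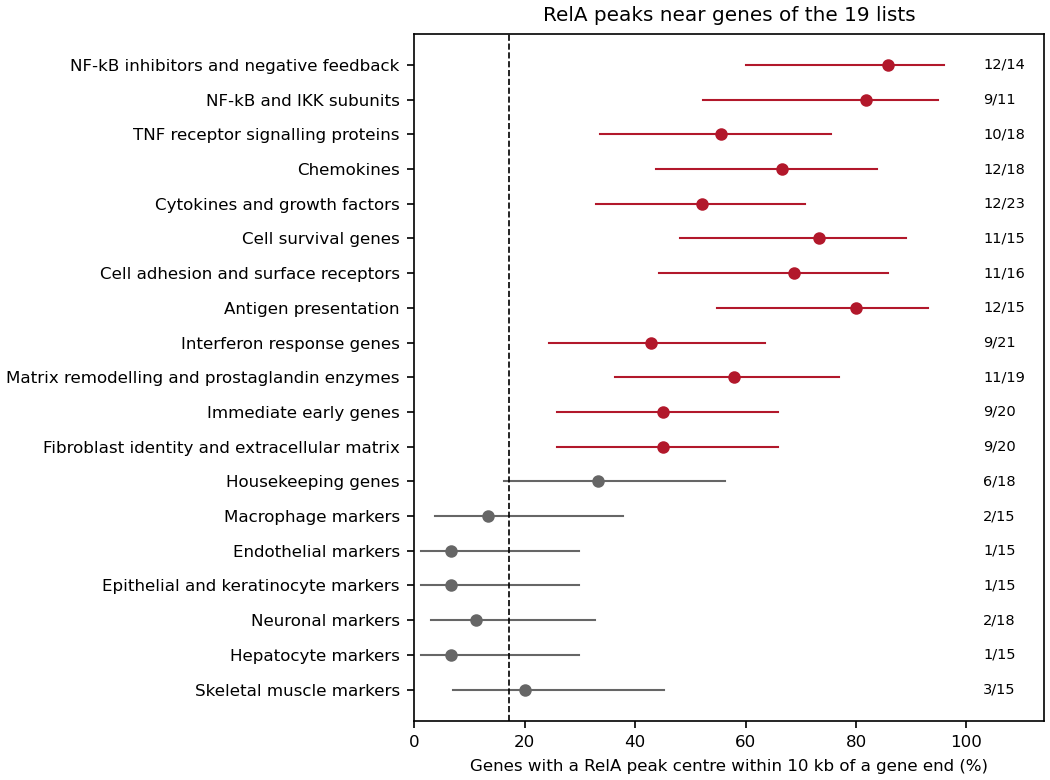
Percentage of genes in each of 19 gene lists with a RelA peak centre within 10 kb of a gene end; points are the observed percentage, lines the Wilson 95% interval, figures at the right the genes near a peak over the genes in the list, and the dashed line the 17.1% of all protein-coding genes. The 12 lists in red had an adjusted p under 0.05 by Fisher's exact test, and the 7 lists in grey did not.

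Cell survival genes were near peaks in 11 of 15 cases (73.3%, Wilson 95% interval 48.0 to 89.1%, Fisher's exact test, adjusted p = 1.63e-05). They included Sod2, the mitochondrial superoxide dismutase gene (0.022 kb), Birc3 (0.138 kb) and the early response gene Ier3 (0.236 kb). Of the genes for matrix remodelling, prostaglandin synthesis and acute-phase proteins, 11 of 19 were near a peak (57.9%, Wilson 95% interval 36.3 to 76.9%, Fisher's exact test, adjusted p = 1.96e-04). The closest were the complement genes C3 (0.063 kb) and Cfb (0.123 kb) and the urokinase gene Plau (0.202 kb). Immediate early genes, which are transcribed within minutes of stimulation, were near a peak in 9 of 20 cases (45.0%, Wilson 95% interval 25.8 to 65.8%, Fisher's exact test, adjusted p = 0.00597), with Atf3 (0.044 kb), Klf6 (0.060 kb) and Ier2 (0.221 kb) the closest. Neither the matrix group (adjusted p = 0.183) nor the immediate early group (adjusted p = 0.0729) passed Fisher's exact test within 1 kb. The immediate early group also did not pass the exact test when the wider peaks alone were kept (adjusted p = 0.0704) or when peaks inside genes were added (adjusted p = 0.0522).

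Fibroblast genes and markers of other cell types served for comparison. Fibroblast identity and extracellular matrix genes were near a peak in 9 of 20 cases (45.0%, Fisher's exact test, adjusted p = 0.00597), with the collagen gene Col5a1 (peak centre at the gene end, chromosome 2, 27886016 to 27886747), the mesenchymal transcription factor gene Prrx1 (0.233 kb) and S100a4 (0.752 kb) the closest. That group did not pass the exact test within 1 kb (adjusted p = 0.190) or when peaks inside genes were added (adjusted p = 0.0522). Housekeeping genes were near a peak in 6 of 18 cases (33.3%, Wilson 95% interval 16.3 to 56.3%, Fisher's exact test, adjusted p = 0.156), among them Sdha (0.117 kb), Polr2a (0.812 kb) and Tubb5 (2.93 kb). This group passed the exact test with a 50 kb window (adjusted p = 0.0229). Markers of cells that a fibroblast culture could also hold were near a peak in 2 of 15 macrophage genes (Aif1 at 1.52 kb and Tyrobp at 4.47 kb, the latter through the Nfkbid peak) and 1 of 15 endothelial genes (Plvap at 2.27 kb), with Fisher's exact adjusted p of 1.00 and 0.584. The counts were 1 of 15 for epithelial and keratinocyte genes (Cldn4 at 4.36 kb), 2 of 18 for neuronal genes (Camk2a at 0.773 kb and Gad1 at 1.75 kb) and 1 of 15 for hepatocyte genes (Cps1 at 3.34 kb), with Fisher's exact adjusted p of 0.584, 0.797 and 0.584. The hepatocyte list fell below other genes with a 50 kb window (Fisher's exact test, adjusted p = 0.0485). Skeletal muscle genes were near a peak in 3 of 15 cases, Myod1 (0.178 kb), Actn3 (0.506 kb) and Casq1 (0.676 kb), with a Fisher's exact adjusted p of 0.797. With lists this short, the intervals were wide, for example 1.19 to 29.8% for the hepatocyte list, and a moderate difference from other genes was not detectable.

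The next question was where peaks accumulated in series. Of all peaks on chromosomes 1 to 19 and X, 1539 (15.7%) had another peak centre within 10 kb, against 763 ± 35.7 (SD) in 1000 random placements on the same chromosomes, 2.02 times as many (two-sided permutation of peak positions, p = 0.002, the smallest the placements allow). The proteasome gene Psma6 on chromosome 12 had the most peaks within 50 kb of its ends, 9, and lay 71.0 kb from Nfkbia. Anxa6, 16.0 kb from Tnip1, Ceacam16, 29.3 kb from Bcl3, and the neighbours Il34 and Sf3b3, which lie 4.54 kb apart, each had 8. The peaks of Il34 and Sf3b3 had the same summed width, 5262 bp, as a set of peaks shared by both genes would. Il34 encodes a cytokine of the macrophage colony-stimulating factor receptor. Cdk6, a cell cycle kinase gene on chromosome 5, also had 8, and 10 peaks lay inside it or within 10 kb. The chemokine genes Ccl2 and Ccl7, 8.26 kb apart on chromosome 11, shared 7 peaks, none within 10 kb of Ccl7. Cuedc1 on chromosome 11 and Ctif on chromosome 18 also had 7. These 4 genes were taken by summed peak width from 11 genes tied at 7 peaks. Peaks were counted around both gene ends, so more sequence was searched for a long gene such as Cdk6 or Ctif than for a short one. The ranking did not allow for this.

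**Figure D2:**
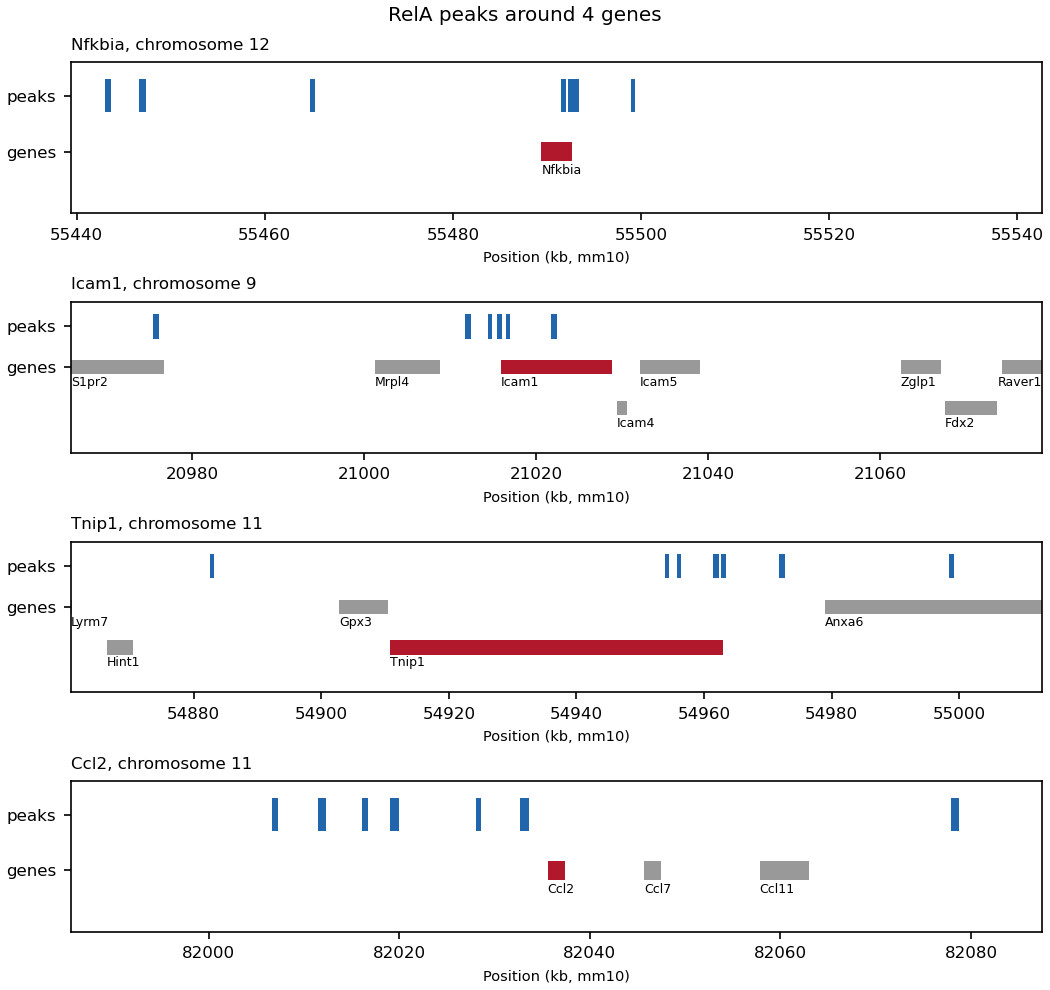
RelA peaks (blue) and protein-coding genes (grey, with the centred gene in red) within 50 kb of Nfkbia, Icam1, Tnip1 and Ccl2, drawn to scale by position in kb on mm10. Within 10 kb of a gene end there were 3 peaks at Nfkbia, 5 at Icam1, 5 at Tnip1 and 2 at Ccl2.

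Location relative to genes was then compared with random placement on the same chromosome. Gene ends held more peaks: 1689 peaks (17.2%) were centred within 1 kb of the end of a gene of any kind, against 6.39 ± 0.250% (SD) in random placements, 2.69 times as many (two-sided permutation of peak positions, adjusted p = 0.003). Regions between genes held fewer, 36.1% against 48.2 ± 0.499%, or 0.750 times as many (permutation, adjusted p = 0.003). Gene bodies held 46.7% against 45.4 ± 0.505%, a ratio of 1.03 (permutation, adjusted p = 0.014). This small excess did not pass the permutation test when gene ends were widened to 5 kb (1.00, p = 0.977) or when peaks were shifted together along each chromosome (1.03, p = 0.0919), and it turned to 0.983 for the wider peaks (p = 0.294). By distance to a protein-coding gene end, the nearest kilobase held 1230 peaks, 4.01 times the random number (central 95% of placements, 3.60 to 4.49). The ratio was 1.03 from 1 to 5 kb and 0.983 from 5 to 10 kb, with ranges that included 1, then 1.09 from 10 to 50 kb and 1.07 from 50 to 100 kb, with ranges starting at 1.06 and 1.02, and 0.624 beyond 100 kb. The median distance to a gene end of any kind was 10499 bp, against 16575 ± 332 bp (SD) for random placement, a ratio of 0.633 (two-sided permutation of peak positions, p = 0.002).

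**Figure D3:**
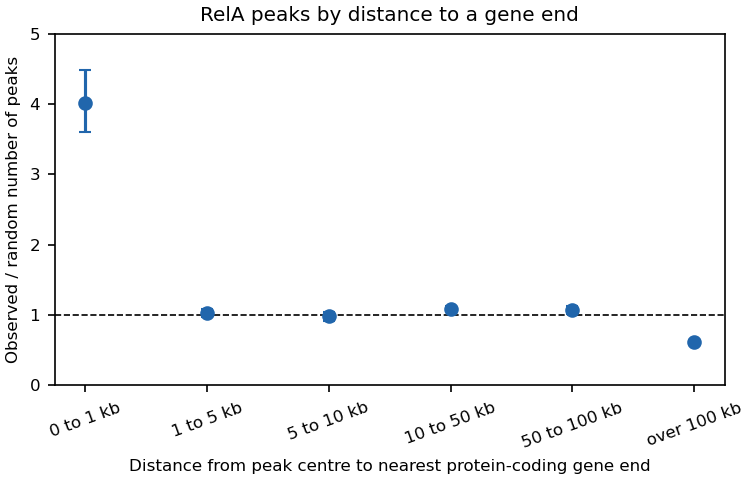
Observed over random number of RelA peaks by distance from the peak centre to the nearest protein-coding gene end; bars give the ratio to the central 95% of 1000 random placements, and the dashed line marks a ratio of 1. The ratio was 4.01 in the nearest kilobase and 0.624 beyond 100 kb.

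Chromosome X held far fewer peaks than its length would give: 135 against 641 expected, a ratio of 0.211 (two-sided permutation of peak positions, adjusted p = 0.00666). Of its protein-coding genes, 40 of 963 (4.15%) were near a peak, against 3650 of 20558 (17.8%) on the autosomes. Chromosome 14 was also low, with 347 peaks against 465 (0.746). Chromosome 11 had the highest ratio, with 635 peaks against 454 (1.40). It and chromosomes 9 (1.21), 15 (1.19) and 10 (1.16) were above random placement at the same adjusted p of 0.00666 (permutation). Chromosomes 2 (1.12) and 13 (1.15) had an adjusted p of 0.00999, and chromosome 18 (1.15) one of 0.0311. The low number on X raises these autosomal ratios. With autosomal peaks placed over the autosomes only, an alternative chosen after seeing the data, chromosomes 11 (1.33) and 14 (0.707) still passed (permutation of peak positions, adjusted p = 0.0190), while chromosomes 2, 9, 10, 13, 15 and 18 did not (1.06 to 1.15, adjusted p from 0.0506 to 0.196).

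**Figure D4:**
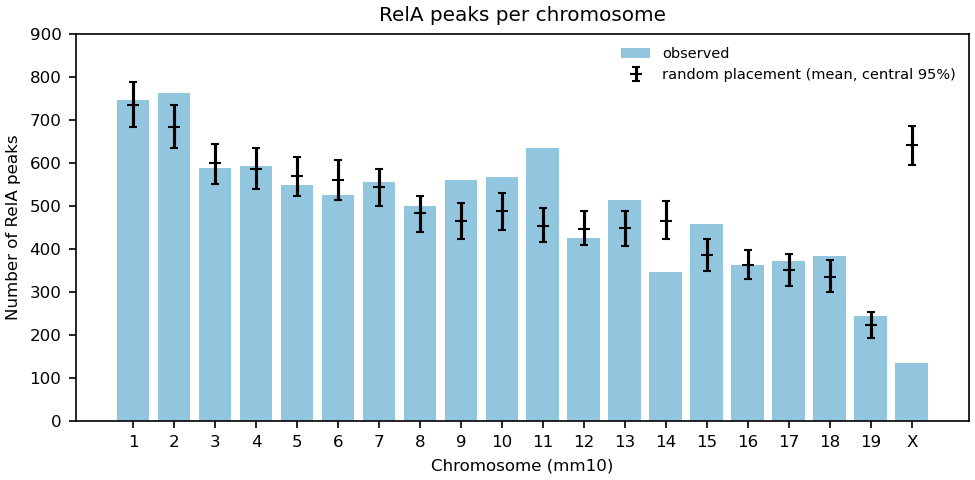
Number of RelA peaks on each mouse chromosome (bars) beside the mean and central 95% of 1000 random placements over all chromosomes (black marks). Chromosome X had 135 peaks against 641 expected and chromosome 11 had 635 against 454.

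The widest peaks were located last, since no peak height was given. The widest, 2015 bp, lay on chromosome 9 from 56417342 to 56419356, 0.127 kb from the end of Peak1, a cytoskeletal pseudokinase gene. Peaks of 1919, 1915, 1914 and 1893 bp were nearest to the zinc finger gene Zfp62 (0.115 kb), Exoc3l4 (1.20 kb), Aup1 (0.720 kb) and Nfatc1 (0.271 kb), which encodes a calcium-regulated transcription factor. Peaks of 1839 bp inside Dnm3, 1834 bp inside Plxna2 and 1824 bp inside Zfhx3 were centred 111, 70.5 and 64.5 kb from the gene end, and a peak of 1837 bp lay 63.3 kb from the growth factor gene Igf1. The remaining peak of the 10 widest, 1955 bp, lay on a contig with no chromosome.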

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

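Outside the main measurement, 6 peaks lay on contigs with no position on a chromosome, where no gene position was used here. The 889 bp peak lay on a contig that is assigned to a chromosome but not placed on it. They were 889, 487, 1497, 1955, 675 and 420 bp wide, and 3 of them stood on a single contig, including the second widest peak of the whole list.

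All tests in this part were chosen after the patterns they address had been seen, and the comparison with housekeeping and fibroblast genes also after the shares it compares. The pattern was the nearness of NF-kB and TNF linked genes to peaks. Gene density and gene length as the whole cause were argued against, because all 12 called lists, the fibroblast list included, stayed past the threshold against random lists matched on both. Peaks at any active gene stay open: 115 of 187 linked genes (61.5%) were near a peak against 15 of 38 housekeeping and fibroblast genes (39.5%), with odds ratios of 2.45 (two-sided Fisher's exact test, p = 0.0184) at 10 kb, 4.04 (p = 0.00255) at 1 kb and 3.66 (p = 6.79e-04) at 5 kb, but 1.45 (p = 0.384) at 50 kb. Lists not written as NF-kB targets also reached shares of 53.3% (p53), 52.9% (clock) and 50% (TGF-beta) at 10 kb. Others were not separated from other genes, with 10.3% for ribosomal protein, 17.4% for proteasome, 31.25% for respiratory chain and 33.3% for cholesterol synthesis genes. RNA levels were not analysed here, so how active any of these genes were is unknown.

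The next pattern was the low number of peaks on chromosome X. Fewer gene ends as the whole cause were argued against, since the observed number was 0.208 times that expected from autosomal rates at the same distances to gene ends, with ratios of 0.178 within 1 kb of an end and 0.213 farther away. The median width of peaks on X minus that on the autosomes was -40 bp (647 against 687 bp, two-sided permutation p = 0.0348). Whether width follows peak number on the autosomes was not tested, and single chromosomes went both ways. Medians were 673 bp on chromosome 11, which had the highest ratio, and 679 bp on the low chromosome 14. The widest median, 709 bp, was on chromosome 9 (ratio 1.21) and the narrowest autosomal one, 665 bp, on chromosome 6 (0.939). A weaker signal on X therefore stays open, as do a single X copy in male embryos, a filter in the authors' processing, and repeats on X, because the sex of the embryos is not given in the sources used here and neither coverage nor sequence was used. The list held no peak on chromosome Y, which does not decide the sex, since any filter on chromosomes is unknown. No biological explanation was tested.

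The last pattern was that the widest peaks lay near linked genes more often. With peaks ranked by width into 4 groups of equal size, 1.51, 1.26, 1.59 and 2.57% from narrowest to widest were within 10 kb of a linked gene, with an odds ratio of 1.72 for the widest against the narrowest group (95% interval 1.14 to 2.59, two-sided Fisher's exact test, p = 0.0112). Binding strength was not measured, so whether width follows it stays open. The widest peaks were also near other genes more often (odds ratio 1.37, 95% interval 1.21 to 1.54), and the ratio of both odds ratios, 1.26 with a 95% interval of 0.820 to 1.93, is too imprecise to separate linked genes from a general shift of wide peaks towards gene ends.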

How the results depend on the processing

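No paired analysis was possible because the peak list has no values per sample; leaving out a replicate and the test by time were not possible for the same reason. Settings fixed beforehand that need a genome sequence (motif windows and backgrounds, base composition matching, peaks with a kappaB site only) were not run. Peaks at gene ends, between genes, the median distance and clusters kept their direction and their side of the threshold under every alternative run for them, and the ratio on chromosome X was 0.211 and 0.208. Over the autosomes only, chromosomes 11 and 14 passed, and the ratios were 1.06 on chromosome 2, 1.15 on 9, 1.10 on 10, 1.09 on 13 and 18 and 1.126 on 15 without passing, since leaving out X raises each expectation. Keeping peaks at or above the median width left 4917 peaks, by construction. The excess inside genes was 1.00 with ends widened to 5 kb, 1.03 by rotation and 0.983 for the wider peaks; the cause was not tested. The number of lists called higher was 12, and 8 (within 1 kb) to 12 under the alternatives. The 12 at 50 kb were not the same lists, since interferon response genes no longer passed and housekeeping genes did. Over all single lists and settings, 124 values kept their sign and their side of the threshold, 16 changed sign without passing, 10 no longer passed and 2 newly passed, as given beside the results. Those that changed sign were among the 7 lists not called, in percentage points above other genes. With the nearest gene within 100 kb only, the values were -0.412 for housekeeping, 10.7 for macrophage, epithelial and neuronal, 24.0 for endothelial and -2.64 for muscle genes. With the wider peaks they were -4.53 for housekeeping, 3.25 for macrophage and -3.42 for muscle genes. Macrophage genes had 1.43 within 5 kb and 18.1 within 50 kb, and endothelial and epithelial genes 4.75 within 50 kb. With peaks inside genes added, an alternative chosen after seeing the data as was rotation, the values were 10.3 for macrophage, 3.61 for epithelial and -3.06 for muscle genes; the cause was not tested, and lists of 15 to 18 genes limit their precision. The counts of peaks depend on library depth, which was unknown.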

Other observations

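In this part, all 16 gene lists and all tests were chosen after the peak list had been seen, though before their values were known, and the genes named were picked after their values were seen. Several further groups were near peaks more often than other genes (two-sided Fisher's exact test, adjusted over the 16 lists). Circadian clock genes were near a peak in 9 of 17 cases (52.9%, exact test, adjusted p = 0.00327), among them Per1 (0.196 kb), Nr1d2 (0.223 kb), Bhlhe40 (0.412 kb) and Per3 (0.485 kb). Targets of p53 were near a peak in 8 of 15 cases (53.3%, exact test, adjusted p = 0.00405), with Btg2 at 0.021 kb, Trp53inp1 at 0.111 kb and Ccng1 at 0.327 kb. TGF-beta pathway genes were near a peak in 9 of 18 cases (exact test, adjusted p = 0.00405), including the receptor gene Tgfbr2 (0.108 kb) and Smad3 (0.215 kb). Actin and focal adhesion genes were near a peak in 9 of 20 cases (45.0%, exact test, adjusted p = 0.00790), with Zyx (0.149 kb), Pxn (0.196 kb) and Actn1 (0.265 kb) the closest. Against random lists matched on gene length and density of gene ends, the clock (permutation, adjusted p = 0.0138), p53 (0.00700) and TGF-beta (0.0138) groups passed and the actin and focal adhesion group did not (0.0510). MicroRNA genes linked to NF-kB or inflammation were near a peak in 10 of 24 cases (41.7%) against 13.5% of other microRNA genes (exact test, adjusted p = 0.00327), including Mir199a-1 (0.395 kb), Mir199a-2 (0.487 kb) and Mir155 (0.943 kb). The microRNA list was not compared with matched lists, and its members Mir143 and Mir145a had the same nearest peak. MicroRNA genes were given as short stretches, such as 84714140 to 84714204 on chromosome 16 for Mir155. Neither end need be where transcription starts, so these distances do not place peaks at microRNA start sites. The same limit holds for the microRNA share by kind of gene below. Mir146, Mir146b and Mir21a were among the members without a peak within 10 kb.

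Other groups were not separated from other genes. YAP and TEAD targets were near a peak in 6 of 15 cases (exact test, adjusted p = 0.0622), with F3 at 0.166 kb, and MAPK phosphatase and Sprouty genes in 5 of 12 (exact test, adjusted p = 0.0721), with Dusp5 at 0.089 kb and Dusp6 at 0.224 kb. Cholesterol synthesis genes, with Hmgcs1 at 0.008 kb, and inflammasome and pattern recognition genes, with Casp4 at 0.068 kb and Nlrp3 at 0.127 kb, were each near a peak in 6 of 18 cases (exact test, adjusted p = 0.143). Mitochondrial respiratory chain genes gave 5 of 16 (exact test, adjusted p = 0.214), ribosomal protein genes 10 of 97 (exact test, adjusted p = 0.126), zinc finger protein genes 61 of 400 (exact test, adjusted p = 0.398), histone cluster genes 12 of 67 (exact test, adjusted p = 0.929) and proteasome subunit genes 8 of 46 (exact test, adjusted p = 1.00). Olfactory receptor genes lay at the other extreme, with 7 of 1109 near a peak (0.631%, exact test, adjusted p = 1.58e-79), and vomeronasal receptor genes had 1 of 352 (0.284%, exact test, adjusted p = 1.08e-26). These sensory receptor genes form clusters of similar copies, so their members are not independent.

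By kind of gene, 17.1% of protein-coding genes were near a peak against 12.3 ± 0.264% (SD) in 100 random placements, a ratio of 1.40. Long noncoding RNA genes gave 16.6% against 11.3 ± 0.306% (ratio 1.48), microRNA genes 14.1% against 7.33 ± 1.26% (1.92) and pseudogenes 5.41% against 7.81 ± 0.306% (0.693). For these 4 kinds the two-sided permutation p was 0.0198, the smallest that the placements allow (adjusted p = 0.0297 over 6 kinds). Transfer RNA genes, 11.4% against 7.37 ± 2.22%, and small nucleolar RNA genes, 6.32% against 7.59 ± 1.18%, were not separated from random placement (permutation, adjusted p = 0.0713 and 0.297). On chromosome X, the genes near a peak were Il13ra1 (4.41 kb) and Timp1 (7.74 kb) among the first 19 lists and the p53 target Eda2r (0.712 kb) among the further lists written gene by gene, which leaves out the receptor, histone, zinc finger, ribosomal protein and proteasome families. Of the other genes in the first 19 lists, Pgk1 (16.0 kb), Syp (109 kb), Hprt (193 kb), Xiap (289 kb), Tab3 (302 kb), Dcx (354 kb) and Ikbkg (478 kb) lay farther away.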
